A study of Homo sapiens with 12 samples.

How the data were processed

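Small RNA from human plasma was sequenced in 12 libraries, 9 from people with cerebral cavernous malformation and 3 from healthy people. The patient libraries fell into 5 labelled CASH and 4 labelled Non CASH, written non-CASH here. The design text gives 9 subjects and 3 controls, so each library was taken as 1 person. P-values of single miRNAs and of measures per library then measure the spread between people. Per the labels' protocols, RNA was isolated with a serum and plasma kit (miRNeasy) and libraries were made with an Illumina small RNA kit. The molecule label reads polyA RNA, which is unusual for a miRNA library.

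The submitters' processing notes name FastQC 0.11.7, cutadapt 1.14, DESeq2 and R 3.4.3 without saying what each was used for. The aligner, the counting tool, the miRNA annotation and the genome build are not given in the sources used here. Each deposited table lists mature miRNAs of 1 library with whole-number counts, per the file headers, in which a read that matches several places is counted in full. A further deposited column holds expected counts, in which such a read is divided over its places. The deposited tables also hold reads scaled to library totals (RPM) against 2 totals, and a number of distinct sequences; neither was used in a test. The lowest count listed in any table was 2, so an unlisted miRNA had 0 or 1 read and was entered as 0.

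The tables held 494 human names, of which 92 were listed in every library. Another 3 names belong to Caenorhabditis elegans and were kept out of totals and tests, a choice made after the data were examined. One of them, cel-let-7-5p, held nearly the same counts as hsa-let-7a-5p, up to 5.70% of all listed counts. Since hsa-let-7a-5p has several human precursors, near-equal counts mean that a read was counted once under each name, not once per copy. In CASH replicate 5 the library total behind the scaled reads was 37371986, against 9544191 counts with reads divided. Counts with reads divided therefore do not add up to all reads, and shares of them are not shares of reads. The remaining human counts per library ran from 1200755 to 37248540, with a median of 2789416. Because hsa-miR-486-5p took most of them, counts outside that miRNA ran from 29936 to 1182278, and this smaller number set the precision for every other miRNA. A true count of 0 allows a share of up to 0.000250% in the library with the lowest total (3 counts of the total), and an unlisted miRNA with 1 read allows more. Intervals on shares are 95% Wilson intervals, and they cover counting error only, since reads without molecular identifiers are not independent molecules. Libraries of 1 group were compared by chi-square, and the closest pair differed by 37.1 per degree of freedom, far above sampling noise, so no library was counted as a duplicate.

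Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM factors. miRNAs were kept by edgeR's expression filter with a minimum count of 10 over the 3 groups, which left 212. One fit of 3 groups gave CASH against non-CASH, CASH against healthy and non-CASH against healthy. A separate fit of 2 groups gave patients against healthy. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Levels are log2 CPM (counts scaled to library size) with a prior count of 2. A fold change from the fit weights libraries by their counts, so it can differ from the difference of mean log2 levels. Standard errors (SE) of log2 fold changes were derived from the test statistic.

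A total of 11 miRNA lists were fixed before the data were examined, as were the comparisons, the tests, the alternatives named first and the rule for naming miRNAs. They covered erythrocyte, platelet, leukocyte, liver, muscle, brain, endothelial and angiogenesis, inflammation, the miR-17-92 cluster and paralogs, the 14q32 imprinted cluster and the let-7 family. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The preset value takes members as nearly independent, so those p-values reflect the spread between miRNAs more than between people. In CASH against non-CASH the estimated correlations were 0.56 for the erythrocyte list and 0.39 for the miR-17-92 and let-7 lists. Fits with a library left out used the preset correlation only. The muscle list kept 1 tested member and the brain list 2, so 9 lists were tested. The erythrocyte list shared 3 of its members with the miR-17-92 list. Other lists overlap too: 6 tested members of the leukocyte list, 5 of inflammation, 3 of platelet and 3 of endothelial and angiogenesis stand in another list. The text names the 10 miRNAs with the smallest p in each comparison when fewer than 10 passed, the most abundant miRNAs, and up to 4 members per list with the smallest p.

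4 measures per library were compared by exact permutation tests of the difference of means, two-sided, with adjustment over 16 tests. They were the log10 total count, the miRNAs detected after thinning to 1200755 counts (mean of 20 draws), the percent of counts in the 10 most abundant miRNAs, and the percent in the erythrocyte list. The planned ratio of hsa-miR-451a to hsa-miR-23a-3p was not computed, because hsa-miR-451a is not analysed here. Alternatives covered other scaling factors, DESeq2 1.42.0, limma-voom, other count filters, removal of the erythrocyte list before scaling, the expected counts rounded to whole numbers, the samples in the fit, and each library left out in turn.

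The edgeR step was tested on simulated data of 212 miRNAs with 60 changed and the spread of the real libraries. In the simulated CASH against non-CASH comparison it recovered 2.5% of 2-fold, 25% of 4-fold and 47.5% of 8-fold changes, and 4.46% of calls were false. At an unadjusted p under 0.05, where the real list calls used adjusted p, camera found 10 of 10 planted lists of 12 miRNAs changed 4-fold. It found 0 of the lists left unchanged. That simulation does not hold the correlation between miRNAs of the real libraries, where camera called at least 1 list in 55 of 99 other splits of the patient libraries. Precursor positions were taken by name from GENCODE 29 (GRCh38), since the tables carry no coordinates. Python 3.11.15, scipy 1.17.1 and pandas 2.3.3 were used for the remaining steps.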

Results

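Plasma miRNA was profiled in people with cerebral cavernous malformation, a lesion of dilated, thin-walled brain vessels also called cavernous angioma, and in healthy people. CASH stands for cavernous angioma with symptomatic hemorrhage. There were 5 CASH libraries, 4 non-CASH patient libraries and 3 healthy libraries. Human miRNA counts ranged from 1609877 to 37248540 in CASH, from 2030341 to 3968611 in non-CASH and from 1200755 to 4058481 in healthy libraries.

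A single miRNA, hsa-miR-486-5p, which is abundant in red blood cells, made up most of the counts in every library when reads are not divided over the places they match. Its share averaged 93.6% ± 5.24 (SD, n = 5) in CASH, 84.0% ± 5.55 (SD, n = 4) in non-CASH and 82.5% ± 10.1 (SD, n = 3) in healthy plasma. The highest shares were 99.02% in CASH replicate 5 (95% Wilson interval 99.01 to 99.02) and 98.1% in CASH replicate 2 (98.12 to 98.16). Dividing reads over their places kept 0.25 of the hsa-miR-486-5p counts. Its share of the divided counts was 82.5% ± 13.1 in CASH (n = 5), 62.6% ± 8.96 in non-CASH (n = 4) and 61.2% ± 14.6 in healthy plasma (n = 3). It was 49.7% in non-CASH replicate 2 and 44.4% in healthy replicate 3. Divided counts add up to fewer than all reads, so these are not shares of reads. Among the remaining counts, hsa-miR-191-5p had the highest mean share either way, at 36.8% ± 7.88 in CASH (n = 5), 41.2% ± 4.66 in non-CASH (n = 4) and 40.1% ± 0.366 in healthy plasma (n = 3). hsa-let-7a-5p followed at 8.64% ± 4.62, 15.1% ± 3.04 and 14.6% ± 5.401 in the same order, a place it loses with reads divided. With reads divided it held 2.58% ± 1.41, 4.66% ± 1.07 and 4.50% ± 1.88, and hsa-miR-10b-5p 8.41% ± 3.61, 4.85% ± 1.83 and 5.41% ± 3.61. CASH replicate 2 held 29936 counts outside hsa-miR-486-5p and listed 112 miRNAs, the fewest of the 12 libraries, so its other miRNAs rest on the least depth.

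**Figure D1:**
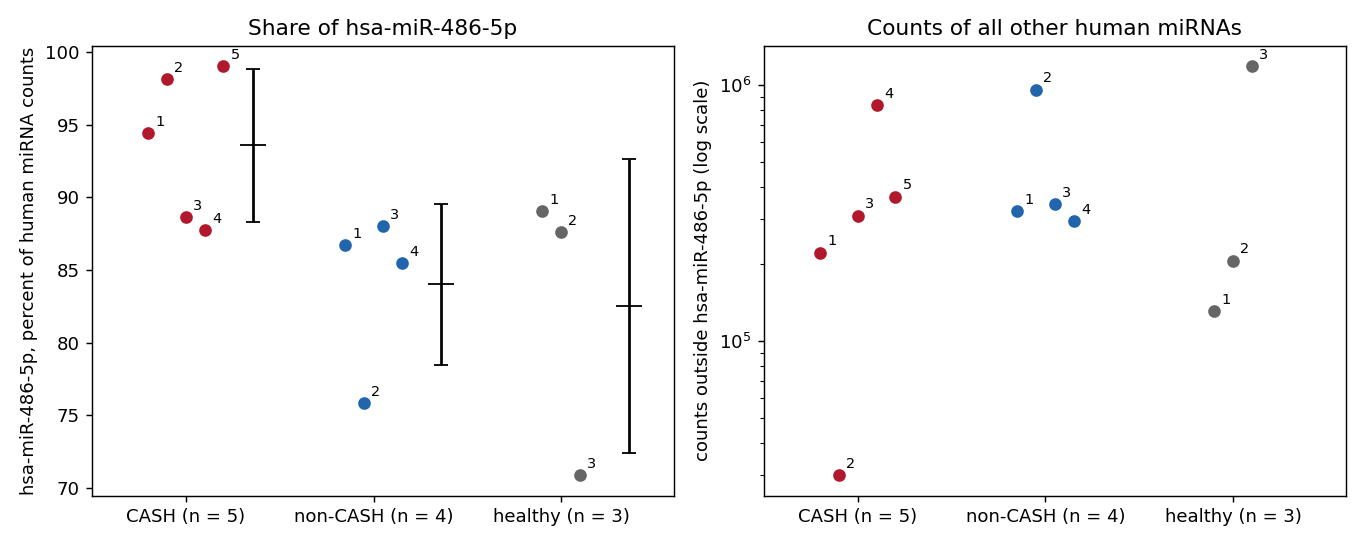
The left panel plots the percent of human miRNA counts in hsa-miR-486-5p, with reads not divided over the places they match, and the right panel the counts of all other human miRNAs on a log scale. Points are libraries numbered by replicate, and bars on the left are mean ± SD. CASH replicates 2 and 5 sit at 98.1% and 99.02%, and CASH replicate 2 has the fewest other counts, 29936.

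hsa-miR-486-5p maps to overlapping precursors on opposite strands of chromosome 8 in GRCh38. MIR486-1 lies at 41660441 to 41660508, in an intron of ANK1, which encodes an ankyrin of the red cell membrane. MIR486-2 lies at 41660444 to 41660507, and no gene on its own strand contains it. Reads from these copies cannot be told apart.

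The first comparison asked which plasma miRNAs distinguish patients with symptomatic hemorrhage from patients without it. miRNAs of the erythrocyte list were higher in CASH than in non-CASH plasma, with a mean log2 fold change of 2.50 over 9 tested members. When libraries were scaled by total counts the mean was 0.16, and the median of all tested miRNAs -1.23. With TMM factors all 9 members had positive values, and 7 passed when adjusted over the list alone, against 0 over all miRNAs tested. The list passed camera with the preset correlation (adjusted p = 7.57e-06). With an estimated correlation its adjusted p = 0.418. Its members with the smallest p were hsa-miR-25-3p at 2.38 (SE 0.63), hsa-miR-486-5p at 2.59 (SE 0.75), hsa-miR-363-3p at 3.93 (SE 1.15) and hsa-miR-16-5p at 2.10 (SE 0.62), the last at -0.19 with total-count scaling. Without CASH replicate 5 hsa-miR-25-3p, hsa-miR-363-3p and hsa-miR-16-5p were at 1.11, 1.90 and 0.76. Each of these 4 miRNAs had an edgeR adjusted p of 0.0991. hsa-miR-25-3p, hsa-miR-486-5p and hsa-miR-16-5p were above the non-CASH mean in 5 of 5 CASH libraries, while hsa-miR-363-3p equalled it in CASH replicate 2, on 2 counts. hsa-miR-486-5p is itself a member and holds most of the list's counts, so its share moves with the list's share by construction. Without CASH replicate 5, the deepest library, the list's mean was 1.15 (adjusted p = 0.000314). Without both CASH replicates 2 and 5, an alternative chosen after the data were examined, it was 0.86 (adjusted p = 0.00227).

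The miR-17-92 cluster and its paralogs, a family linked to cell proliferation, averaged 1.60 over 8 tested members in CASH against non-CASH. With total-count scaling the mean was -0.29, and the median of all tested miRNAs -1.23. With TMM factors all 8 values were positive and 3 passed when adjusted over the list alone, against 0 over all miRNAs tested. Camera gave an adjusted p of 0.00274 with the preset correlation, and adjusted p = 0.418 with an estimated correlation. 3 of its members also stand in the erythrocyte list, and without them the mean was 1.21 (adjusted p = 0.0714). With the erythrocyte list removed before scaling the mean was 1.19 (adjusted p = 0.133). hsa-miR-25-3p, hsa-miR-93-5p and hsa-miR-106b-3p come from 1 cluster in an intron of MCM7 on chromosome 7, between 100093560 and 100094074 in GRCh38. Their log2 fold changes were 2.38 (SE 0.63), 1.07 (SE 0.66) and 2.63 (SE 0.78), with adjusted p-values of 0.0991, 0.614 and 0.0991, and without CASH replicate 5 they were 1.11, -0.13 and 1.36. With total-count scaling hsa-miR-93-5p was at -0.83. Without CASH replicate 5 the list's mean was 0.73 (adjusted p = 0.0313), and without healthy replicate 2, which changed the tested members to 10, it was 0.96 (adjusted p = 0.0107).

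The let-7 family, whose members are widely expressed and restrain growth genes, was lower in CASH than in non-CASH plasma. Its mean log2 fold change was -0.64 over 9 tested members. With total-count scaling the mean was -1.61, and the median of all tested miRNAs -1.23. With TMM factors 8 of the family's 9 members had negative values. Of them 0 passed when adjusted over the list alone or over all miRNAs tested. hsa-let-7e-5p was at -1.24 (SE 0.50), hsa-let-7d-5p at -1.05 (SE 0.46), hsa-let-7a-5p at -0.96 (SE 0.45) and hsa-miR-98-5p at -1.06 (SE 0.52). All of these 4 were below the non-CASH mean in 5 of 5 CASH libraries, and lowest in CASH replicate 5, where hsa-let-7e-5p was at 4.19 log2 CPM against 7.42 to 7.77 in the other 4. Without that library the list's mean was -0.47 (adjusted p = 0.0313). The list's adjusted p was 0.0262 with the preset correlation, and adjusted p = 0.609 with an estimated correlation. The call ended when CASH replicate 1 or 4, non-CASH replicate 1, or any healthy replicate was left out, with adjusted p-values from 0.0589 to 0.0969. It also ended with the erythrocyte list removed before scaling (adjusted p = 0.106) and with only the 2 patient groups in the fit (adjusted p = 0.0757).

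**Figure D2:**
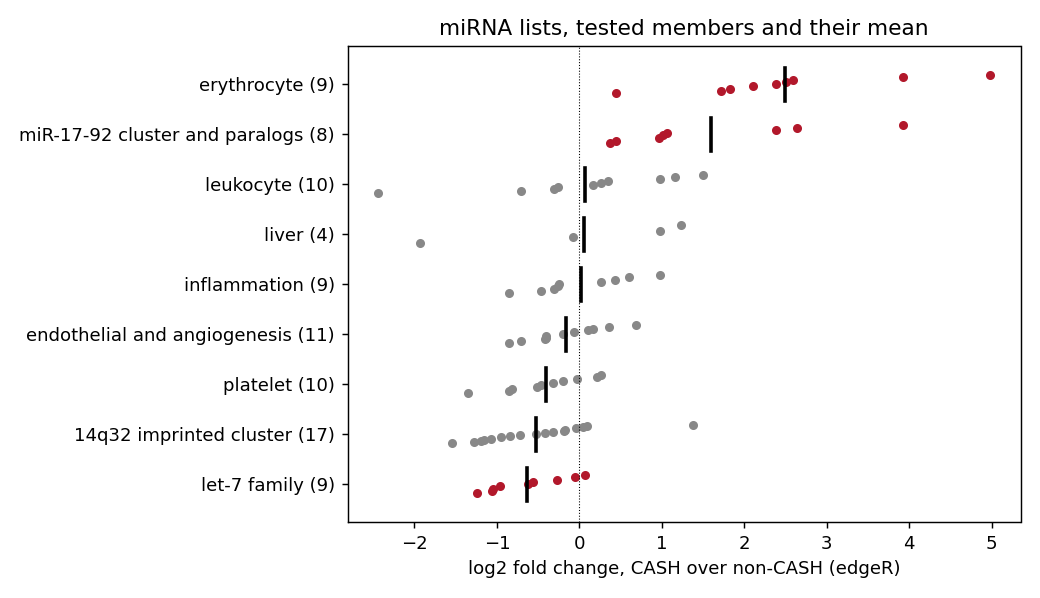
Each row is a miRNA list with its number of tested members. Points are members' log2 fold changes, CASH over non-CASH, and the black bar is their mean. Red rows passed camera with the preset correlation, and all 9 erythrocyte members lie above 0.

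Lists for other cells and tissues did not pass in this comparison. The platelet list averaged -0.41 over 10 members (adjusted p = 0.0714), the 14q32 imprinted cluster -0.52 over 17 (adjusted p = 0.148) and the endothelial and angiogenesis list -0.16 over 11 (adjusted p = 0.335). The leukocyte list averaged 0.07 over 10 members (adjusted p = 0.830), the liver list 0.05 over 4 (adjusted p = 0.617) and the inflammation list 0.02 over 9, with a median of -0.25 (adjusted p = 0.830). Members with an unadjusted p under 0.05 went both ways. In the platelet list hsa-miR-21-5p and hsa-miR-28-3p were at -0.85 (SE 0.36) and -0.82 (SE 0.37), below the non-CASH mean in 5 of 5 CASH libraries. In the leukocyte list hsa-miR-142-5p, hsa-miR-150-5p and hsa-miR-181a-5p were at 1.16 (SE 0.53), 1.497 (SE 0.72) and 0.98 (SE 0.33). They were above the non-CASH mean in 3, 3 and 5 of 5 CASH libraries. hsa-miR-21-5p and hsa-miR-181a-5p also stand in the inflammation list. With total-count scaling hsa-miR-142-5p and hsa-miR-181a-5p were at -0.59 and -0.31. hsa-miR-122-5p, made mainly in liver, was at -1.93 (SE 0.80), with 1.003 and 2.28 as the SDs of its log2 levels in CASH (n = 5) and non-CASH (n = 4). Without non-CASH replicate 3 its value was 0.55, and without CASH replicate 5 hsa-miR-28-3p and hsa-miR-142-5p were at -0.54 and 0.49. The platelet list passed without CASH replicate 3 (adjusted p = 0.0426) or without non-CASH replicate 3 (adjusted p = 0.0476). The 14q32 list passed without CASH replicate 1 (adjusted p = 0.0451), CASH replicate 3 (adjusted p = 0.0426) or non-CASH replicate 3 (adjusted p = 0.0147).

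Further single miRNAs had small p-values. hsa-miR-15a-5p, which lies beside MIR16-1 in the DLEU2 gene on chromosome 13 (50049119 to 50049201), was at 3.18 (SE 0.92, adjusted p = 0.0991). hsa-miR-183-5p was at 2.66 (SE 0.82, adjusted p = 0.117). hsa-miR-185-5p and hsa-miR-144-5p, both in the erythrocyte list, were at 2.50 (SE 0.82) and 4.98 (SE 1.72), each with an adjusted p of 0.156. Without CASH replicate 5 hsa-miR-15a-5p, hsa-miR-183-5p and hsa-miR-185-5p were at 1.76, 1.08 and 1.20. hsa-miR-144-5p rests on 15 counts in the 4 non-CASH libraries and 532 in the 5 CASH libraries. With edgeR 0 of the tested miRNAs passed in CASH against non-CASH, while 25 had an unadjusted p under 0.05 (18 higher, 7 lower) against 10.6 that chance gives. DESeq2 called 12, all higher, limma-voom 0, and edgeR without CASH replicate 3 called 7. Of all tested miRNAs, 10 had no overlap between the groups (4.72%, against 1.59% by chance), hsa-miR-25-3p and hsa-let-7e-5p among them.

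**Figure D3:**
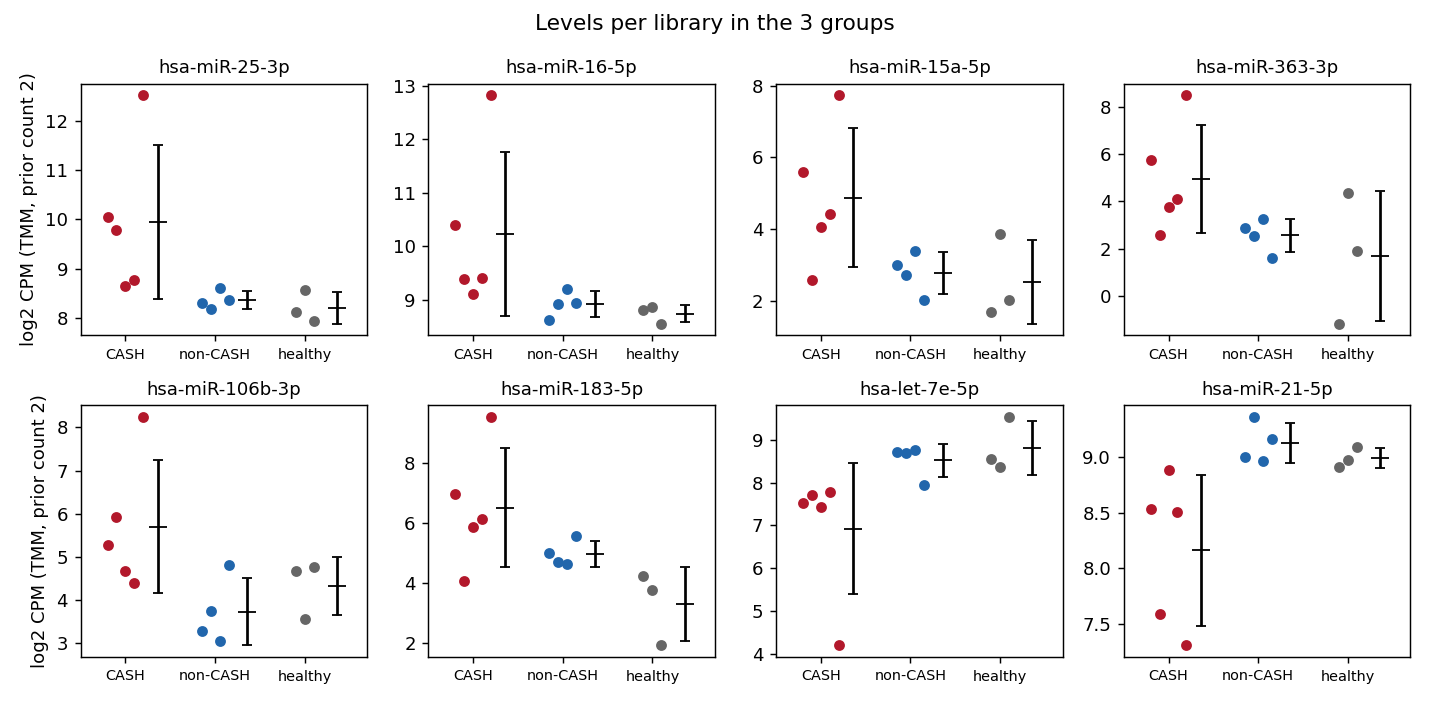
Each panel plots the log2 CPM of 1 miRNA per library in the 3 groups, with mean ± SD beside the points. CASH replicate 5, the fifth red point, holds the highest level of the first 6 miRNAs and the lowest level of the last 2.

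Measures per library were compared by exact tests. The 10 most abundant miRNAs held 98.5% ± 1.13 of counts in CASH (n = 5) and 96.5% ± 1.15 in non-CASH (n = 4), with every CASH value above every non-CASH value (exact permutation p = 0.0159, the smallest these groups can give, which adjusts to 0.254 over 16 tests). The erythrocyte list held 94.0% ± 5.03 (n = 5) and 84.9% ± 5.18 (n = 4) (exact permutation p = 0.0317, adjusted p = 0.254). Of the counts with reads divided over their places it held 83.5% ± 12.7 and 64.1% ± 8.55 (exact permutation p = 0.0317). That share is made up mostly of hsa-miR-486-5p and is not a share of reads. Outside hsa-miR-486-5p, the other erythrocyte miRNAs made up 11.4% ± 9.96 of counts in CASH (n = 5) and 5.38% ± 0.861 in non-CASH (n = 4), by an exact permutation test with p = 0.111. Without CASH replicate 5 the CASH mean was 6.997% ± 1.698 (n = 4), and the difference 1.62 in place of 6.02. Much of this share is 1 member, hsa-miR-92a-3p, whose log2 fold change was 0.44. It alone held 6.67% ± 3.87 of counts outside hsa-miR-486-5p in CASH (n = 5) and 4.44% ± 0.858 in non-CASH (n = 4). Log10 total counts were 6.73 ± 0.524 and 6.44 ± 0.124 (exact permutation p = 0.365), and miRNAs detected after thinning were 193 ± 55.8 and 231 ± 33.5 (exact permutation p = 0.286). That difference ran from -53.3 to -17.9 with each library left out. Thinned outside hsa-miR-486-5p, the numbers detected were 178 ± 38.4 and 183 ± 7.20 (exact permutation p = 0.937).

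The second comparison asked how plasma of all patients differs from that of healthy people. The erythrocyte list averaged 1.79 (adjusted p = 0.0909) and the miR-17-92 list 1.29 (adjusted p = 0.0909), with 9 of 9 and 8 of 8 positive values, and neither passed. With total-count scaling the miR-17-92 mean was -0.05, and the median of all tested miRNAs -0.53. The means were 0.72 and 0.62 without CASH replicate 5, and without healthy replicate 3 the miR-17-92 mean was 2.47. hsa-miR-4732-3p had 2 counts in the 3 healthy libraries and was above their mean in 8 of 9 patients. Its share of counts outside hsa-miR-486-5p was higher in patients by a ratio of 84.4, with a 95% exact counting interval of 23.2 to 699.2 that leaves out the spread between people. Without CASH replicate 5 the ratio was 43.5, and without healthy replicate 3 no healthy count was left. hsa-miR-183-5p was at 3.49 (SE 1.21), hsa-miR-107 at 1.77 (SE 0.74), hsa-miR-501-3p at 1.51 (SE 0.71) and hsa-miR-19b-3p at 3.10 (SE 1.499), each above the healthy mean in 9 of 9 patients. hsa-miR-25-3p, hsa-miR-16-5p and hsa-miR-15a-5p were at 1.88 (SE 0.88), 1.69 (SE 0.84) and 2.44 (SE 1.24), each above it in 8 patients, hsa-miR-15a-5p in CASH replicate 2 on 2 counts. hsa-miR-139-5p was at -3.24 (SE 1.57) on 17 patient and 27 healthy counts, and hsa-mir-1273a-5p_novel at -3.22 (SE 1.33) on 52 and 66. Leaving out CASH replicate 5 put hsa-miR-183-5p, hsa-miR-107, hsa-miR-25-3p, hsa-miR-16-5p and hsa-miR-15a-5p at 2.17, 1.13, 0.85, 0.66 and 1.20. Without healthy replicate 1 hsa-mir-1273a-5p_novel was at -2.12. hsa-miR-19b-3p was unlisted in healthy replicates 1 and 2. Without healthy replicate 3 it was at 7.57 with no healthy count left, so that size is not a measured fold change. It enters the miR-17-92 mean of 2.47. With edgeR 0 miRNAs passed, with a smallest adjusted p of 0.571, and 8 had an unadjusted p under 0.05 against 10.6 by chance. DESeq2 called 1 miRNA, hsa-miR-4732-3p, and limma-voom 0.

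The other lists did not pass between patients and healthy people either. The let-7 family averaged -0.38 (adjusted p = 0.168), the 14q32 cluster -0.66 (adjusted p = 0.579), the liver list 1.07 (adjusted p = 0.735) and the leukocyte list -0.05 (adjusted p = 0.754). The platelet list averaged 0.24 (adjusted p = 0.883), the endothelial and angiogenesis list 0.10 (adjusted p = 0.883) and the inflammation list 0.07 with a median of -0.27 (adjusted p = 0.579). Single libraries moved these calls. The let-7 mean was -0.24 without CASH replicate 2 or 5, -0.64 without healthy replicate 1 and 0.16 without healthy replicate 3. Without non-CASH replicate 4 the erythrocyte and miR-17-92 lists passed (adjusted p = 0.0424 for each). Without healthy replicate 1 the 14q32 list passed at -1.44 with the preset correlation (adjusted p = 2.13e-07). Its estimated correlation with all libraries was 0.52, and a fit with that estimate was not run without this library. Without healthy replicate 3 the brain list, then with 3 tested members, passed at -2.65 (adjusted p = 0.0420).

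CASH against healthy plasma gave the same 3 list calls as CASH against non-CASH with the preset correlation, and 0 with the estimated correlation or fry. The erythrocyte list averaged 2.39 over 9 members, and 0.16 with total-count scaling, with 9 positive values, 4 past the threshold when adjusted over the list alone and 0 over all miRNAs tested (adjusted p = 0.00148, and 0.530 with the estimated correlation). The miR-17-92 list averaged 1.73 over 8 members, and -0.23 with total-count scaling, with 8 positive values, 2 past the threshold when adjusted over the list alone and 0 over all miRNAs tested (adjusted p = 0.00683, and 0.530 with the estimated correlation). The let-7 family averaged -0.72 over 9 members, and -1.88 with total-count scaling, with 8 negative values and 0 past the threshold either way (adjusted p = 0.0308, and 0.636 with the estimated correlation). The let-7 call also ended with only the 2 groups in the fit (adjusted p = 0.105), and without the shared members the miR-17-92 list, at 1.51, did not pass. Both comparisons use the same CASH libraries, so their agreement is not independent evidence. With total-count scaling the median of all tested miRNAs was -1.19 in CASH against healthy plasma. Without CASH replicates 2 and 5 no list passed, and the erythrocyte mean was 0.96 (adjusted p = 0.0528).

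hsa-miR-183-5p, above the healthy mean in 5 of 5 CASH libraries, was at 4.17 (SE 1.01, edgeR adjusted p = 0.0534). hsa-miR-4732-3p, with 2 counts in healthy plasma, had the same adjusted p. Its share of counts outside hsa-miR-486-5p was higher in CASH by a ratio of 145.6 (95% exact counting interval 39.99 to 1207). That interval leaves out the spread between people. The ratio was 64.7 without CASH replicate 5, 260.7 without CASH replicate 4, and had no healthy count without healthy replicate 3. CASH replicate 5 held most CASH counts of hsa-miR-4732-3p. Its precursor lies on chromosome 17 at 28861655 to 28861730 in GRCh38, beside that of hsa-miR-144 at 28861533 to 28861618, and both overlap an exon of the noncoding gene AC024267.1. hsa-miR-25-3p was at 2.53 (SE 0.71), hsa-miR-16-5p at 2.29 (SE 0.70), hsa-miR-501-3p at 2.03 (SE 0.65, and -0.13 with total-count scaling), hsa-miR-107 at 2.20 (SE 0.71) and hsa-miR-15a-5p at 3.17 (SE 1.05). hsa-miR-486-5p was at 2.51 (SE 0.84), hsa-miR-363-3p at 3.55 (SE 1.28), hsa-miR-106b-3p at 2.09 (SE 0.85, and -0.48 with total-count scaling) and hsa-miR-19b-3p at 3.47 (SE 1.70). hsa-let-7e-5p, hsa-let-7f-5p, hsa-let-7d-5p and hsa-let-7a-5p were at -1.59 (SE 0.53), -0.85 (SE 0.34), -1.11 (SE 0.49) and -1.01 (SE 0.48). Without CASH replicate 5 hsa-miR-183-5p was at 2.62, hsa-miR-25-3p at 1.30, hsa-miR-16-5p at 0.99, hsa-miR-107 at 1.24, hsa-miR-15a-5p at 1.84, hsa-miR-363-3p at 1.63, hsa-miR-106b-3p at 0.84 and hsa-let-7a-5p at -0.65. Without healthy replicate 3 hsa-miR-19b-3p was at 7.98, and the 4 let-7 members at -0.96, -0.46, -0.21 and -0.33. No healthy count of hsa-miR-19b-3p was then left, so the size of 7.98 is not a measured fold change. With edgeR 0 miRNAs passed, and 22 had an unadjusted p under 0.05 (14 higher, 8 lower) against 10.6 by chance. DESeq2 called 8, all higher, limma-voom 0, and edgeR called 2 without CASH replicate 1, 1 without CASH replicate 2, 4 without CASH replicate 3 and 1 without non-CASH replicate 4.

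The remaining lists did not pass in CASH against healthy plasma. The 14q32 cluster averaged -0.96 (adjusted p = 0.347), the liver list 0.96 (adjusted p = 0.552) and the leukocyte list -0.12 with a median of 0.04 (adjusted p = 0.730). The platelet list averaged 0.03 with a median of -0.27 (adjusted p = 0.552), the endothelial and angiogenesis list 0.01 with a median of -0.18 (adjusted p = 0.586) and the inflammation list 0.05 with a median of -0.62 (adjusted p = 0.552). Without healthy replicate 1 the 14q32 list passed at -1.83 with the preset correlation (adjusted p = 3.46e-06). The let-7 call ended without CASH replicate 1 or 4, non-CASH replicate 3 or healthy replicate 3, and without CASH replicate 5 the erythrocyte and miR-17-92 means were 1.10 (adjusted p = 0.0192) and 0.91 (adjusted p = 0.0450). Without healthy replicate 3 the let-7 mean was -0.12 and the miR-17-92 mean 2.80. The latter includes hsa-miR-19b-3p at 7.98, with no healthy count left.

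Non-CASH against healthy plasma had the fewest miRNAs with an unadjusted p under 0.05 in edgeR, 1 against 8 to 25 in the other comparisons. Groups did not overlap for 12 miRNAs (5.66%, against 5.71% by chance). The erythrocyte list averaged -0.10 (adjusted p = 0.851), the miR-17-92 list 0.13 with a median of -0.17 (adjusted p = 0.851) and the let-7 family -0.08 (adjusted p = 0.851). The platelet list averaged 0.43, the leukocyte list -0.18, the endothelial and angiogenesis list 0.16 and the inflammation list 0.03 with a median of -0.16, each with an adjusted p of 0.851. The liver list averaged 0.91 (adjusted p = 0.885) and the 14q32 cluster -0.43 (adjusted p = 0.969). hsa-miR-4732-3p had 71 counts in non-CASH and 2 in healthy plasma, a ratio of 28.1 with a 95% exact counting interval of 7.50 to 236.7. That interval leaves out the spread between people, and the edgeR adjusted p was 0.998. The ratio was 48.3 without non-CASH replicate 2, 16.9 without non-CASH replicate 3, and had no healthy count without healthy replicate 3. hsa-miR-375 was at 1.91 (SE 1.11), hsa-miR-320a at 0.84 (SE 0.49), hsa-miR-183-5p at 1.51 (SE 0.91), hsa-miR-1271-5p at 2.72 (SE 1.77) and hsa-miR-19b-3p at 2.46 (SE 1.65). hsa-miR-29a-3p, hsa-miR-150-5p, hsa-miR-7-5p and hsa-miR-4433b-5p were at -3.52 (SE 1.98), -1.36 (SE 0.78), -3.23 (SE 1.92) and -1.23 (SE 0.75). hsa-miR-29a-3p was at -6.86 without non-CASH replicate 2, hsa-miR-375 and hsa-miR-320a at 1.23 and 0.34 without non-CASH replicate 4, and hsa-miR-150-5p at -0.44 without healthy replicate 2. hsa-miR-4433b-5p was at -0.77 without healthy replicate 1, and hsa-miR-1271-5p and hsa-miR-19b-3p at 7.30 and 6.83 without healthy replicate 3. No healthy count of hsa-miR-1271-5p or hsa-miR-19b-3p was then left, and without non-CASH replicate 2 no non-CASH count of hsa-miR-29a-3p. The sizes of 7.30, 6.83 and -6.86 are therefore not measured fold changes. With edgeR 0 miRNAs passed, the smallest adjusted p was 0.998, and 1 had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0. With the preset correlation the 14q32 list passed at -1.29 without healthy replicate 1 (adjusted p = 9.39e-06) and at 0.96 without healthy replicate 2 (adjusted p = 0.0473), and the brain list at -2.67 without healthy replicate 3 (adjusted p = 0.0177).

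Measures per library gave exact permutation p-values from 0.143 to 0.864 against healthy plasma. The erythrocyte list held 83.5% ± 9.75 of counts in healthy plasma (n = 3), and exact permutation tests gave p = 0.264 against patients, 0.179 against CASH and 0.800 against non-CASH. The 10 most abundant miRNAs held 96.4% ± 1.93 in healthy plasma (n = 3), with exact permutation p = 0.336, 0.143 and 0.857 in the same order. miRNAs detected after thinning were 205.5 ± 56.6 (n = 3), with exact permutation p = 0.864, 0.821 and 0.457. Log10 total counts were 6.30 ± 0.274 (n = 3), with exact permutation p = 0.218, 0.286 and 0.400. An exact test of 4 non-CASH against 3 healthy libraries cannot give a p below 0.0571.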

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

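The tests of 1 low-yield library, of members without shared reads and of CASH replicate 2, and every alternative with hsa-miR-486-5p set apart, were chosen after the data were examined. The tests of low yield and of members without shared reads were chosen after their results were seen.

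Camera with the preset correlation called 3 lists between the patient groups, and with the estimated correlation or fry it called 0. The erythrocyte list averaged 2.50 (adjusted p = 0.418 with the estimated correlation). The miR-17-92 list averaged 1.60 (adjusted p = 0.418), and the let-7 family -0.64 (adjusted p = 0.609). With total-count scaling the miR-17-92 mean was -0.29, and the median of all tested miRNAs -1.23. Other splits of the 9 patient libraries gave erythrocyte means with a median size of 1.82 and up to 2.59, and 5 of 100 were at least as large as the real 2.50, the real one included, so chance was not excluded.

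The platelet list had a median of -0.392 in CASH against non-CASH, with a sign-test interval over members of -0.85 to 0.21. The leukocyte list had a median of 0.21 (-0.71 to 1.16). Both medians fell short of the rise that blood cells of every kind left in CASH plasma were expected to give. These values are relative to the other tested miRNAs, so a rise shared by most of them would not show. The intervals leave out the spread between people, so blood cells of every kind were not excluded. Reads counted at several identical copies were argued against, since the divided share of each member differed between the patient groups by at most 0.056 log2 units. Dividing thus scales each member by nearly the same factor in both groups, which nearly cancels in a fold change. The 107.7% of the mean left with reads divided is therefore no separate support. The 4 members without such reads, hsa-miR-25-3p, hsa-miR-363-3p, hsa-miR-144-5p and hsa-miR-144-3p, averaged 3.25 (t interval over members 0.90 to 5.60). All 4 were measured in the same people, so that interval leaves out the spread between people. CASH replicate 5 carried much of the mean, as 45.93% remained without that library, although the list still passed camera with the preset correlation (adjusted p = 0.000314, and from 1.29e-06 to 0.747 over all alternatives). The difference in symptomatic hemorrhage between the groups stays open as an untested explanation, and red cell RNA released when blood was drawn or handled stays open too.

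hsa-miR-486-5p stood at 98 to 99 percent of counts in CASH replicates 2 and 5. Of the counts with reads divided over their places, which leave out part of the reads, it held 93.9 and 96.9%. In CASH replicate 5 the other 8 erythrocyte miRNAs lay above the other CASH libraries by a median of 3.417 log2 units relative to all tested miRNAs. Each library was compared with the rest of its own group, and any other library reached at most 0.60. Red cell RNA is a candidate explanation in CASH replicate 5. In CASH replicate 2 the same median was -0.795, with an interval from -2.23 to 3.49. Its reference includes CASH replicate 5, as for every other CASH library, which lowers these medians by construction. By share, the other erythrocyte miRNAs held 8.86% of counts outside hsa-miR-486-5p in CASH replicate 2. That was above every library except CASH replicate 5, at 29.02%, and CASH replicate 1 followed at 7.95%. Much of such a share is 1 member, hsa-miR-92a-3p, which averaged 6.67% of counts outside hsa-miR-486-5p in CASH. More red cell RNA and other sources therefore cannot be told apart in CASH replicate 2 at its depth. That library held 29936 counts outside hsa-miR-486-5p, the next lowest 131359. This restates its high share and does not tell a low yield of other miRNAs from other sources.

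Single libraries stood apart from the rest of their group in 10 of 78 tests, where chance gives about 3.9. In 3 of the 10 the other libraries all had 0 counts, so any listed count would stand apart and those 3 cannot be set against chance. CASH replicate 5 stood apart in 4. The erythrocyte miRNAs other than hsa-miR-486-5p held 29.02% of its counts outside that miRNA, against 5.18 to 8.86% in the other CASH libraries. Its hsa-let-7e-5p level was 4.19 log2 CPM against 7.42 to 7.77, its hsa-miR-107 level 8.95 against 5.92 to 6.46, and its hsa-miR-4433b-5p level 2.04 against 4.48 to 5.28. In CASH replicate 4 hsa-miR-139-5p was at 0.12 log2 CPM, while the other 4 CASH libraries listed none.

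Among non-CASH libraries, the 10 most abundant miRNAs held 94.8% of counts in replicate 2, against 96.99 to 97.15% in the rest. hsa-miR-139-5p and hsa-miR-29a-3p were at 0.71 and 0.50 log2 CPM in that library and unlisted in the other 3. hsa-let-7e-5p was at 7.95 log2 CPM in replicate 4 against 8.68 to 8.76, and hsa-miR-93-5p at 6.41 in replicate 1 against 5.76 to 5.81.

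cel-miR-39-3p, a worm miRNA often added to plasma as a reference, was listed at 3.02 CPM in CASH replicate 1 on 12 counts, above the healthy maximum of 1.66. It was listed in 4 of the 12 libraries.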

How the results depend on the processing

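Of 55 log2 fold changes of single miRNAs, 1326 values under other choices kept their direction and side of the threshold in 1251 cases, passed the threshold in 54 and reversed in 21. No miRNA passed in the main fits, so no call could be lost. A kept value can be much smaller, as with hsa-miR-16-5p at 0.76 without CASH replicate 5 against 2.10 with all libraries. Differential expression rested on 5, 4 and 3 libraries, and outside hsa-miR-486-5p the lowest library had 29936 counts, so a miRNA of low level in CASH replicate 2 may read as 0. Sensitivity of measures per library was judged on exact permutation p-values without adjustment. The alternatives built on hsa-miR-451a were not run. No paired analysis was possible because replicate numbers follow the order of accession and link no libraries across groups.

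With total-count scaling, CASH against non-CASH reversed for hsa-miR-16-5p (-0.19), hsa-miR-181a-5p (-0.31), hsa-miR-93-5p (-0.83), hsa-miR-142-5p (-0.59) and the miR-17-92 list (-0.29). That list also reversed in patients (-0.0465) and in CASH (-0.23) against healthy plasma, the latter with hsa-miR-501-3p (-0.13) and hsa-miR-106b-3p (-0.48). Total-count scaling moved the median of all tested miRNAs from -0.08 to -1.23 in CASH against non-CASH, which the larger share of hsa-miR-486-5p in CASH accounts for in part by construction. In CASH against healthy plasma that median moved from -0.01 to -1.19, and in patients against healthy plasma from 0.08 to -0.53.

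A covariate for the ratio of hsa-miR-16-5p to hsa-miR-23a-3p was added after the data were examined. It removes erythrocyte differences by construction, since hsa-miR-16-5p is in that list. With it CASH against non-CASH gave -0.23 for hsa-miR-25-3p, -0.28 for hsa-miR-486-5p, -0.23 for hsa-miR-16-5p, -0.44 for hsa-miR-93-5p, 0.15 for hsa-let-7a-5p, 0.28 for hsa-miR-98-5p and -0.23 for hsa-miR-142-5p, with 0 lists. The erythrocyte list was at 0.01 there, at -0.10 in patients against healthy and at -0.14 in CASH against healthy plasma. The last comparison gave -0.10 for hsa-miR-25-3p, -0.0675 for hsa-miR-16-5p, -0.36 for hsa-miR-486-5p, -0.54 for hsa-miR-106b-3p and 0.15 for hsa-let-7a-5p, with 0 lists. limma-voom reversed hsa-miR-150-5p in non-CASH against healthy plasma (0.23); the cause was not tested.

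Counts of miRNAs past the threshold were 0 with edgeR, and 12, 1, 8 and 0 with DESeq2 in CASH against non-CASH, patients against healthy, CASH against healthy and non-CASH against healthy. Without a filter they were 10, 2, 6 and 0. CASH against healthy plasma gave 3 with upper-quartile factors, 1 with only its 2 groups in the fit and 1 without CASH replicates 2 and 5. Lists past the threshold fell from 3 to 0 with the estimated correlation and with fry in both CASH comparisons, to 0 in CASH against non-CASH when the erythrocyte list was removed before scaling, and to 0 in CASH against healthy plasma without CASH replicates 2 and 5. The causes were not tested.

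With each library left out in turn, CASH against non-CASH called 0 to 7 miRNAs and 2 to 5 lists, hsa-miR-93-5p ran from -0.13 to 1.49 and hsa-miR-122-5p from -2.32 to 0.55. Patients against healthy called 0 to 2 lists, with let-7 means from -0.64 to 0.16. CASH against healthy called 0 to 4 miRNAs and 2 to 4 lists, and non-CASH against healthy 0 to 1 lists. Differences in miRNAs detected ran from -21.2 to 34.6 in patients and from -38.2 to 17.6 in CASH against healthy plasma, the latter 11.3 when thinned outside hsa-miR-486-5p. The percent in the 10 most abundant ran from -1.02 to 0.762 in non-CASH against healthy plasma (-0.103 with reads divided over their places), and in CASH against healthy plasma the 3 most abundant differed by 4.55 (exact permutation p = 0.0357). The erythrocyte percent ran from 6.60 to 10.6 in CASH against non-CASH and from -4.18 to 4.58 in non-CASH against healthy plasma. Without hsa-miR-486-5p these differences were 6.02 and -0.416. Fewer libraries also raise the smallest p an exact test can give.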

Other observations

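In CASH against non-CASH plasma, the chromosome 13 neighbours hsa-miR-15a-5p and hsa-miR-16-5p were at 3.18 and 2.10 on the log2 scale, and at 1.76 and 0.76 without CASH replicate 5. hsa-miR-16-5p was at -0.19 with total-count scaling, and it has a further copy in SMC4 on chromosome 3. On chromosome X, hsa-miR-363-3p (134169378 to 134169452 in GRCh38) was at 3.93, and at 1.90 without CASH replicate 5.

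Other splits of the same libraries were counted for each comparison, with edgeR and camera. For CASH against non-CASH, 100 splits were drawn, and 100 called at least the real 0 miRNAs, with up to 8 in another split. At least the real 3 lists were called by 23 of the 100, with up to 5. For patients against healthy people, 100 of 220 splits were drawn, and 100 called at least the real 0 miRNAs, with up to 16, and 100 at least the real 0 lists, with up to 5. For CASH against healthy plasma, 56 of 56 splits called at least 0 miRNAs, with up to 14, and 10 of 56 at least the real 3 lists, with up to 4. For non-CASH against healthy plasma, 35 of 35 splits called at least 0 miRNAs, with up to 1, and 35 of 35 at least 0 lists, with up to 1. Chance was not excluded for the 2 counts of 3 lists. The other 6 real counts were 0, which any split equals or exceeds, so these splits decide nothing about them. Most splits called 0 miRNAs (median 0), and any were called by 6 of 99, 17 of 99, 6 of 55 and 2 of 34 other splits in the order above. At least 1 list was called by 55 of 99, 65 of 99, 41 of 55 and 14 of 34 other splits, so camera with the preset correlation often calls lists in these libraries when the groups are rearranged. The splits with 8, 14 or 16 calls may reflect a structure of the samples in those splits, which was not tested.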
